A study of Mus musculus with 12 samples.

How the data were processed

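RNA from 12 mouse samples in 4 groups of 3 was measured, each sample on its own whole-transcript array. The deposited values are log2 signals, 1 per probe set and array. Per the submitters' processing notes they came from Affymetrix Expression Console 1.2.1 with RMA, which corrects background, makes the distributions of all arrays equal by quantile normalization and summarises each probe set by median polish. The values were checked: each array had nearly the same distribution, no pair of columns was identical, and every array was used as deposited, without further scaling in the principal fit. No detection calls were among the files analysed here, so genes with a mean below 8.01, the median of all tested values, in both groups compared are described as having low signal. No depth applies to arrays, and the number of arrays, 3 per group, limits the precision. The label protocol names a human array, whereas the probe set identifiers match the mouse gene-level platform named in the table header, and the mouse gene table was used.

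Of the 35556 probe sets, 23410 stood in the gene table, 21789 of them with 1 gene and 1621 with several, and 12146 had no gene. For 21698 of the probe sets with 1 gene the gene identifier matched the mouse RefSeq annotation, which served only to check gene names, and 0 symbols needed updating. Probe sets with several genes or none were left out, so that genes known only from these, such as Cdkn1a, Trp53 and Isg15, are not analysed here. For the 999 genes with several probe sets the one with the highest mean over the 12 arrays was used, which left 19938 genes. No level of one probe set was set against that of another, since probe sets differ in how they bind.

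A linear model with a mean per group was fitted to all 12 arrays with limma 3.58.1 under R 4.3.3, with moderated variances, for 5 comparisons: null_EC against WT_EC, null_EB against null_EC, and ESC against each of null_EC, null_EB and WT_EC. P-values were adjusted by Benjamini-Hochberg over all genes within a comparison, and a gene was called at an adjusted p below 0.05. Genes that were also at least 2-fold different were counted apart. The named genes follow a rule written before the data were examined: Cd47, Myc, Pou5f1, Sox2, Klf4 and Nanog in every comparison, the 8 genes with the largest increase and the 8 with the largest decrease among called genes whose groups did not overlap (predicted genes, clone names, olfactory and vomeronasal receptors and small RNAs left out), and for each gene list up to 2 called members with the largest increase and up to 2 with the largest decrease. Genes named outside this rule are said to be so.

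The 22 gene lists were fixed before the data were examined: pluripotency network, endothelial identity, lymphatic endothelium, fibroblast and smooth muscle, lung epithelium and mesothelium, immune cells, ectoderm and neural, mesoderm, endoderm, Myc targets and ribosome biogenesis, DNA replication and mitosis, cell cycle inhibitors and senescence, p53 targets, unfolded protein and amino acid stress response, cholesterol synthesis, hypoxia and glycolysis, interferon response, autophagy, CD47 and thrombospondin pathway, Hox genes, sex-linked genes and immediate early genes. Some genes stand in several lists. Each list was tested against the other genes with camera of limma at a preset correlation between genes of 0.01, adjusted over the lists of a comparison, and again with a correlation estimated from the data. The members past the threshold were counted after adjustment over all genes and after adjustment over the list alone. The test fry, which asks whether the genes of a list move one way, was run beside it. The position of each array on the line from the mean of WT_EC (0) to the mean of ESC (1) was computed over the genes called and at least 4-fold different between these groups, with end points that leave out the array placed, and compared by a 2-sided exact permutation test. The smallest p that 3 against 3 allows is 0.1. Overlaps of calls between comparisons that share the null_EC arrays were set beside 100 simulated data sets with unchanged groups and beside the counts independent calls would give.

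On simulated data with 100 genes changed by 2-fold and 100 by 4-fold, the percent of genes recovered at 2-fold was 94 in null_EC against WT_EC, 99 in null_EB against null_EC, 98 in ESC against null_EC, 95 in ESC against null_EB and 98 in ESC against WT_EC. At 4-fold it was 100 in each but ESC against WT_EC, where it was 98. With the spread of each group as in the data, 135 unchanged genes were called in null_EC against WT_EC and 182 in ESC against WT_EC, and 0, 2 and 3 in null_EB against null_EC, ESC against null_EC and ESC against null_EB. A simulated group placed at 0.3 on the line was recovered at 0.298.

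The alternatives were a filter on dim genes (log2 of at least 6 on at least 3 arrays), every probe set tested by itself, arrays shifted so that the median of the housekeeping genes was equal, cyclic loess, a variance trend with robust moderation, array weights, a fit of the 6 arrays compared, the replicate number as a block, an estimated correlation for the lists, for the positions, axis genes at least 2-fold different or without the pluripotency, endothelial identity and DNA replication lists, at least 2-fold changes for the overlaps, and leaving out each array in turn. The housekeeping scale genes measured were 7 of the 11 chosen. A fit without the WT_EC arrays was added after the data had been seen.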

Results

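Gene expression was measured in mouse cells on 12 arrays, 3 for each of 4 groups. WT_EC were lung endothelial cells of wild-type C57Bl/6 mice, and null_EC were lung endothelial cells without CD47, the cell surface receptor that binds thrombospondin-1 and SIRP alpha. The null_EB group held embryoid bodies, free aggregates of cells, which per the labels formed within 24 to 36 h when CD47 null endothelial cells passaged for 6 months were moved to medium without serum. ESC was the embryonic stem cell line V6.5, kept in 15% serum with the self-renewal factor LIF at 1000 IU/ml. Culture medium and growth form therefore differed between groups along with the cell type. The Y-linked genes Eif2s3y and Uty had high signal only in ESC, so sex may differ as well. A passage time is given only for null_EB, so null_EB and null_EC may also differ in passage. The labels do not say whether replicates were separate animals or cultures, so the spread between these samples could be technical only. The p-values use an error pooled over all 4 groups, and the WT_EC arrays spread most. In comparisons with WT_EC the p-values therefore tend to be too small. Simulations with few changed genes, drawn independently of each other, called 135 unchanged genes in null_EC against WT_EC and 182 in ESC against WT_EC. More changed genes loosen the adjusted threshold, so these counts do not give the number of false calls in the data. Values are log2 signals, group values are means ± SD of 3 arrays, and errors of differences are standard errors from limma.

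The arrays had medians between 7.66 (WT_EC 2) and 7.75 (WT_EC 3). Pairs of arrays within null_EC, null_EB and ESC correlated across probe sets at 0.994 or more, and pairs within WT_EC at 0.954 to 0.968, where probe sets are not independent replicates. The median SD of a gene was 0.213 in WT_EC, 0.0652 in null_EC, 0.0770 in null_EB and 0.0847 in ESC. The WT_EC arrays differed from each other in whole gene groups. The median of the immune cells list was 8.92 on WT_EC 3, 6.90 on WT_EC 1 and 6.24 on WT_EC 2, whereas on WT_EC 2 the interferon response list stood highest, at 11.08 against 9.92 on WT_EC 1. The hypoxia and glycolysis list was 11.78 on WT_EC 1 against 10.39 and 10.66 on WT_EC 2 and WT_EC 3. The first principal component, with 63.4% of the variance, set ESC apart from the other arrays, and the next, with 16.9%, set WT_EC 1 and WT_EC 3 furthest from the null groups.

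Cd47, the targeted gene, had signals of 12.59, 11.29 and 12.48 on the WT_EC arrays, 10.98, 11.11 and 11.02 on the null_EC arrays, 10.99, 10.89 and 10.93 on the null_EB arrays, and 11.23, 10.96 and 11.33 on the ESC arrays. It was 2.12-fold lower in null_EC (11.03 ± 0.0675) than in WT_EC (12.12 ± 0.721; log2 difference -1.09, SE 0.270, adjusted p = 0.0228), and it did not differ between null_EB and null_EC (log2 -0.10, SE 0.270, adjusted p = 0.950). The files do not say which exons the probe set covers, so signal from outside a disrupted part of the gene would remain and checks nothing. The call of Cd47 was lost with the 6 arrays alone (adjusted p = 0.181), with the housekeeping shift (adjusted p = 0.0563), and without WT_EC 1 (adjusted p = 0.0504), WT_EC 3 (adjusted p = 0.0584) or any null_EC array (adjusted p from 0.0607 to 0.0858).

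**Figure D1:**
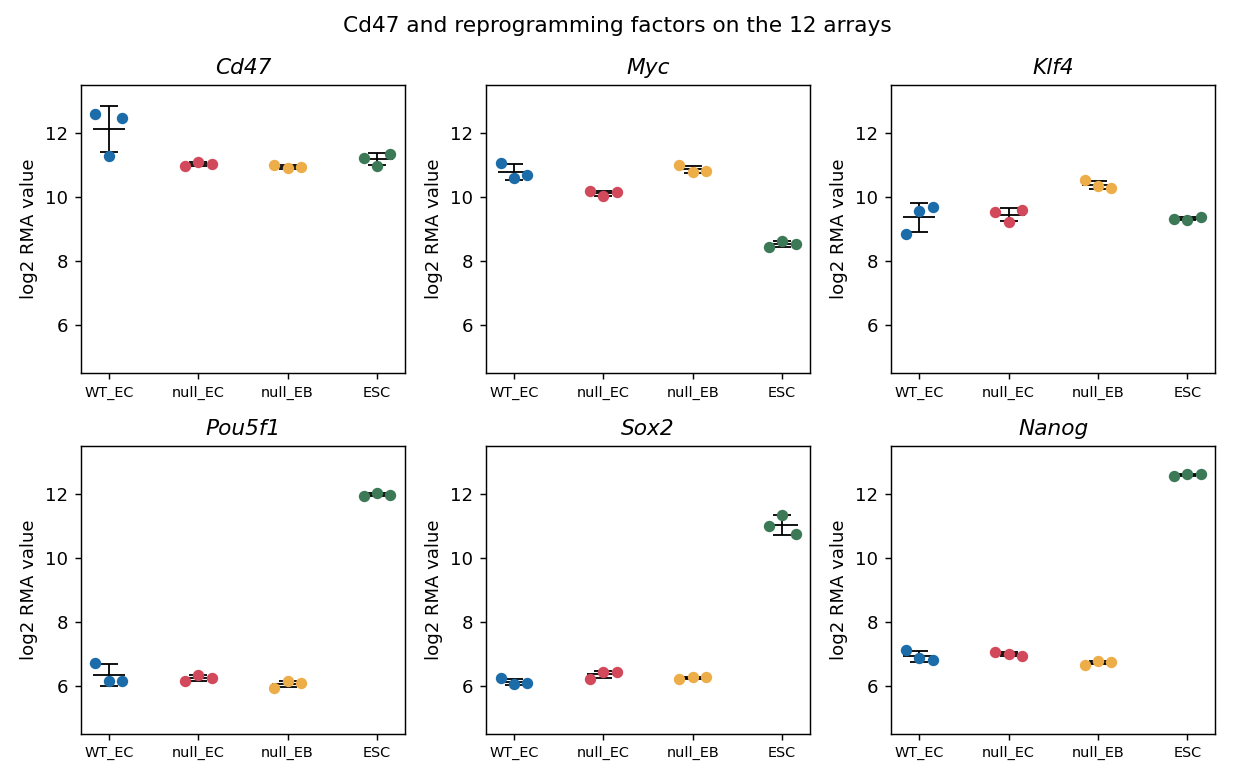
Signal of Cd47 and of the stem cell factors Myc, Klf4, Pou5f1, Sox2 and Nanog on each array (log2 signal, points) with the mean and SD of each group of 3 arrays. Pou5f1, Sox2 and Nanog were high only on the ESC arrays, while Myc was higher in null_EB (10.87) than in null_EC (10.11) and lowest in ESC (8.53).

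The title of the series names Myc and other stem cell transcription factors. Myc, a growth-promoting transcription factor, was lower in null_EC (10.11 ± 0.0820) than in WT_EC (10.77 ± 0.252; log2 -0.66, SE 0.120, adjusted p = 0.00473), and this call was lost with the 6 arrays alone (adjusted p = 0.0766). Myc rose again in null_EB (10.87 ± 0.104; log2 0.75, SE 0.120, adjusted p = 0.00503). In ESC it was lower than in any other group, 3.00-fold against null_EC (adjusted p = 9.97e-07), 5.04-fold against null_EB (adjusted p = 5.59e-08) and 4.72-fold against WT_EC (adjusted p = 8.9e-08). Klf4, another reprogramming factor, did not differ between null_EC and WT_EC (log2 0.08, SE 0.190, adjusted p = 0.851) and rose 1.90-fold in null_EB (10.37 ± 0.127 against 9.45 ± 0.213, adjusted p = 0.0190), a call lost on leaving out any null_EC or null_EB array. Pou5f1, Sox2 and Nanog, the core of the pluripotency network, had low signal in both endothelial groups and in null_EB. None of them passed the test in null_EC against WT_EC (adjusted p = 0.757, 0.313 and 0.725) or in null_EB against null_EC (log2 -0.19, -0.10 and -0.26, adjusted p = 0.585, 0.838 and 0.123). Nanog was called lower in null_EB with the 6 arrays alone, with array weights and without WT_EC 1, and also in a fit without the WT_EC arrays that was added after the data had been seen. In ESC the signals of Pou5f1 (11.97 ± 0.0394), Sox2 (11.02 ± 0.301) and Nanog (12.58 ± 0.0347) were 60.4-fold, 27.3-fold and 58.0-fold higher than in null_EB.

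In null_EC, labelled as CD47 null endothelial cells, the genes of DNA replication and mitosis were lower than in WT_EC. Some endothelial and mesothelial genes also differed between arrays of these groups, as given below. Genotype and the cell make-up of the samples were therefore not separated in this comparison. Bub1, a spindle checkpoint kinase, was 7.69-fold lower (6.49 ± 0.453 against 9.44 ± 0.526, adjusted p = 0.000114) and Ccna2, the cyclin of S phase and mitotic entry, was 6.18-fold lower (8.12 ± 0.440 against 10.75 ± 0.439, adjusted p = 0.000162). Of the 44 measured members 37 fell, 0 rose and 7 did not pass, and adjusted over the list alone 41 fell and 1 rose. The median member changed by -1.29 (camera adjusted p = 4.17e-35; adjusted p = 0.0577 with an estimated correlation). Of 37 Hox genes, which set position along the body axis, 13 were higher, 0 lower and 24 did not pass (17 higher adjusted over the list alone). The higher ones included Hoxc13 (4.92-fold, 9.22 ± 0.101 against 6.92 ± 0.0629, adjusted p = 4.72e-06) and Hoxd8 (3.98-fold, adjusted p = 0.0161). Their median was 0.38 (camera adjusted p = 1.83e-06; adjusted p = 0.0577 with an estimated correlation).

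Single genes moved much further. The largest increases in null_EC were those of Gabrb1, a subunit of the GABA-A receptor (15.0-fold, 10.69 ± 0.0730 against 6.79 ± 0.406, adjusted p = 7.36e-06), and Itm2a (13.1-fold, adjusted p = 0.000205). The sialomucin Podxl (7.94-fold, adjusted p = 4.72e-06) and the adhesion receptor Adgrg1 (7.83-fold, adjusted p = 5e-06) rose as well. Next came the homeobox gene Emx2 (6.96-fold, adjusted p = 7.37e-05), Gabra4, another GABA-A receptor subunit (6.75-fold, adjusted p = 0.000938), the Ras activator Rasgrp3 (6.06-fold, adjusted p = 0.00523) and the mucin Muc16 (5.43-fold, adjusted p = 0.00446). The largest decreases were those of the chemokine Cxcl13, 61.7-fold lower (6.83 ± 0.183 against 12.77 ± 0.396, adjusted p = 8.4e-08), and the monooxygenase Fmo2 (log2 -4.81, adjusted p = 0.000574). They were followed by the acute phase genes Serpina3n (21.0-fold, adjusted p = 1.47e-07) and Lcn2 (17.7-fold, adjusted p = 8.58e-06). Then came Adam23 (16.7-fold, adjusted p = 1.98e-06), the growth factor Fgf7 (15.6-fold, adjusted p = 1.98e-06), the cytokine Il6 (14.9-fold, adjusted p = 0.0157) and the sodium channel Scn7a (14.4-fold, adjusted p = 0.0242). The folds of these 2 genes depended on which WT_EC arrays were counted. Il6 was at 10.79, 5.89 and 9.40 on WT_EC 1, WT_EC 2 and WT_EC 3 and Scn7a at 5.88, 8.81 and 11.33. The log2 difference of Il6, -3.90, was -2.85 without WT_EC 1 and -5.30 without WT_EC 2, and that of Scn7a, -3.85, was -5.25 without WT_EC 1 and -2.52 without WT_EC 3.

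The endothelial identity list had 2 of 44 members higher and 4 lower (2 and 5 adjusted over the list alone). The VEGF receptor Kdr was 3.67-fold higher (10.70 ± 0.161 against 8.82 ± 0.460, adjusted p = 0.000108), whereas Calcrl, the receptor for adrenomedullin, was 5.84-fold lower (adjusted p = 1.91e-05) and Flt1, another VEGF receptor, 2.68-fold lower (adjusted p = 0.000313). Adm, which encodes adrenomedullin itself, fell 10.1-fold (adjusted p = 0.000807). The list median was -0.16 (camera adjusted p = 0.00373, and 0.580 with an estimated correlation). Of 18 endothelial core genes, listed after the values had been seen, 1 was called higher and 1 lower. Cdh5 and Esam, named outside the rule, were not called. On the WT_EC arrays Cdh5 was at 9.10, 6.85 and 9.52 and Esam at 10.3, 6.97 and 9.53. In null_EC they were at 7.09 to 7.27 and 7.25 to 7.37. None of the 9 lymphatic endothelium genes was called by limma, and 1 had an unadjusted p below 0.05, with a median of -0.55 (camera adjusted p = 0.00537; adjusted p = 0.474 with an estimated correlation). In the immune cells list 1 of 23 members was called, Cd14, the receptor for bacterial lipopolysaccharide, at 2.25-fold lower (adjusted p = 0.0450), and 0 were called adjusted over the list alone (median -0.86, camera adjusted p = 0.00106; adjusted p = 0.474 with an estimated correlation). Without array WT_EC 3, where the immune list stood at 8.92, none of these 3 lists passed (camera adjusted p = 0.470, 0.166 and 0.0748). The endothelial identity median was also high on WT_EC 1 (7.72), beside 7.89 on WT_EC 3 and 7.19 to 7.28 in null_EC. WT_EC 2 lay below every null_EC array in the endothelial identity (7.05), lymphatic (6.86) and immune (6.24) medians.

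In the unfolded protein and amino acid stress response list 13 of 38 members rose and 2 fell (15 and 2 adjusted over the list alone), with the stress transcription factor Ddit3 3.16-fold higher (adjusted p = 0.00106), the endoplasmic reticulum stress gene Creld2 2.53-fold higher (adjusted p = 0.00224) and the serine synthesis gene Psat1 2.11-fold lower (adjusted p = 0.00622). The list median was 0.35 (camera adjusted p = 0.000273; adjusted p = 0.474 with an estimated correlation). Of the 21 cholesterol synthesis genes 6 rose and 0 fell (14 rose adjusted over the list alone), including Lss (2.39-fold, adjusted p = 0.0196) and Sqle (1.89-fold, adjusted p = 0.0417), with a median of 0.70 (camera adjusted p = 6.73e-05; adjusted p = 0.474 with an estimated correlation). Arrays overlapped in both lists: the stress list median was 10.90 on WT_EC 1 beside 10.73 to 10.97 in null_EC, and the cholesterol synthesis median was 10.89 on WT_EC 3 beside 10.39 to 11.06. Autophagy genes had 5 of 31 higher and 0 lower (9 adjusted over the list alone), with Gabarapl1 1.81-fold higher (adjusted p = 0.0134; list median 0.27, camera adjusted p = 0.000452; adjusted p = 0.374 with an estimated correlation). The hypoxia and glycolysis list passed only narrowly (2 of 33 higher, 1 lower, the same adjusted over the list alone, camera adjusted p = 0.0489; adjusted p = 0.786 with an estimated correlation), and leaving out any single array other than WT_EC 1 or null_EC 3 ended the call.

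Immediate early genes, the quick transcriptional response to growth signals, had 11 of 32 lower and 0 higher (13 adjusted over the list alone), with Egr2 4.80-fold lower (adjusted p = 0.00907) and Ccn2 2.98-fold lower (adjusted p = 0.00329; list median -0.63, camera adjusted p = 3.51e-09; adjusted p = 0.110 with an estimated correlation). The interferon response list had 5 of 31 lower (6 adjusted over the list alone), led by Cxcl10 at 7.82-fold (adjusted p = 0.00376) and Zbp1 at 4.97-fold (adjusted p = 0.0103; list median -0.85, camera adjusted p = 2.1e-08; adjusted p = 0.474 with an estimated correlation). The interferon medians of WT_EC 1 (9.92) and WT_EC 2 (11.08) lay above those of null_EC (9.01 to 9.25), and that of WT_EC 3 did not. Fibroblast and smooth muscle genes had 9 of 38 lower and 0 higher (12 lower and 1 higher adjusted over the list alone), with the matrix genes Dpt 7.38-fold lower (adjusted p = 0.000724) and Lum 5.44-fold lower (adjusted p = 0.0355; list median -0.58, camera adjusted p = 2.84e-08; adjusted p = 0.110 with an estimated correlation). Of the 25 p53 targets 7 fell and 0 rose (9 and 2 adjusted over the list alone), with Eda2r 2.56-fold lower (adjusted p = 0.000619; list median -0.32, camera adjusted p = 0.000273; adjusted p = 0.103 with an estimated correlation). The cell cycle inhibitors and senescence list had 6 of 17 lower and 1 higher (7 and 1 adjusted over the list alone). The members that fell included the secreted factors Il6 and Mmp3 (7.74-fold, adjusted p = 0.0360), the latter at 12.40, 8.10 and 11.53 on the WT_EC arrays and no longer called without WT_EC 1 or WT_EC 3, while Igfbp3 rose 3.87-fold (adjusted p = 0.000127; list median -0.22, camera adjusted p = 0.000914; adjusted p = 0.0577 with an estimated correlation). On the arrays, the fibroblast and smooth muscle median was 9.25 on WT_EC 1 beside 9.17 to 9.31 in null_EC, and the p53 median was 9.14 on WT_EC 2 beside 9.10 to 9.18. In the CD47 and thrombospondin pathway 4 of 20 fell and 2 rose (9 and 2 adjusted over the list alone). Sirpa, which encodes a ligand of CD47, fell 2.53-fold (adjusted p = 7.67e-05), and the thrombospondin receptor Cd36, of low signal, 5.61-fold (adjusted p = 0.0196; list median -0.32, camera adjusted p = 0.00210; adjusted p = 0.209 with an estimated correlation). Its median was 9.62 on WT_EC 3 beside 9.48 to 9.65 in null_EC.

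The remaining 7 lists did not pass in null_EC against WT_EC. The pluripotency network had 2 of 39 members higher, Tfcp2l1 (3.42-fold, adjusted p = 0.000291) and Alpl (3.12-fold, adjusted p = 0.000419), and 1 lower, Mybl2 (1.69-fold, adjusted p = 0.0223; camera adjusted p = 0.953). The lung epithelium and mesothelium list had 4 of 25 higher, with Krt14 at 3.87-fold and the mesothelial gene Upk3b at 2.14-fold (camera adjusted p = 0.981). Of 9 mesothelium genes listed after the values had been seen, 4 were higher and 0 lower, with a median of 0.52. Mesoderm genes had 1 of 26 higher, Runx1 at 3.11-fold, and 4 lower, with Osr1 at 6.53-fold and Foxf1 at 3.15-fold (camera adjusted p = 0.147). In the endoderm list 1 of 23 was higher, Gata4 at 2.29-fold (camera adjusted p = 0.876). Myc targets and ribosome biogenesis had 1 of 45 higher, Rrp1b, and 1 lower, Dkc1 (camera adjusted p = 0.423). This list was called lower without WT_EC 3 (adjusted p = 0.000211). None of the 26 ectoderm and neural genes (3 at an unadjusted p below 0.05 in limma, camera adjusted p = 0.303) and none of the 6 sex-linked genes (0 at an unadjusted p below 0.05, camera adjusted p = 0.876) was called. These counts were the same adjusted over the list alone except that mesoderm had 2 higher and 5 lower and Myc targets had 0 lower.

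In all, 2615 of 19938 genes were called in null_EC against WT_EC, 1619 higher and 996 lower, and 652 of them at least 2-fold (223 higher, 429 lower). In 2603 of the 2615 the groups did not overlap. A call already favours such separation, so this adds no support. The 10% that chance gives for 3 against 3 holds only for unselected genes. Camera called 15 of the 22 lists at the preset correlation and 0 with an estimated correlation, 6 at an unadjusted p below 0.05, while fry called 9. The share of calls that were higher was 61.9%, against 45.0% with the housekeeping shift, 38.9% with cyclic loess and 49.5% with array weights, so which direction held more calls depended on the scaling. The 6 arrays alone gave 588 calls, all among the 2615. Leaving out WT_EC 2 gave 5435, and leaving out null_EC 1, null_EC 2 or null_EC 3 gave 1335, 1648 or 1449. The calls of Mmp3 and Sqle were lost in 13 of 20 other settings, that of Cd14 in 12 and that of Lum in 11. Of the 65 genes the rule named here, 32 lost their call with the 6 arrays alone. Those named above were Cd47, Myc, Rasgrp3, Muc16, Il6, Scn7a, Mybl2, Lum, Krt14, Upk3b, Cd14, Osr1, Foxf1, Rrp1b, Dkc1, Mmp3, Creld2, Psat1, Lss, Sqle, Cxcl10, Zbp1, Gabarapl1, Cd36, Hoxd8 and Egr2. In 15 of the 65 the fold changed by more than 1.5 times when 1 array was left out, a WT_EC array in each: Itm2a, Rasgrp3, Muc16, Fmo2, Il6, Scn7a, Lum, Osr1, Mmp3, Adm, Cxcl10, Zbp1, Cd36, Hoxd8 and Egr2.

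**Figure D2:**
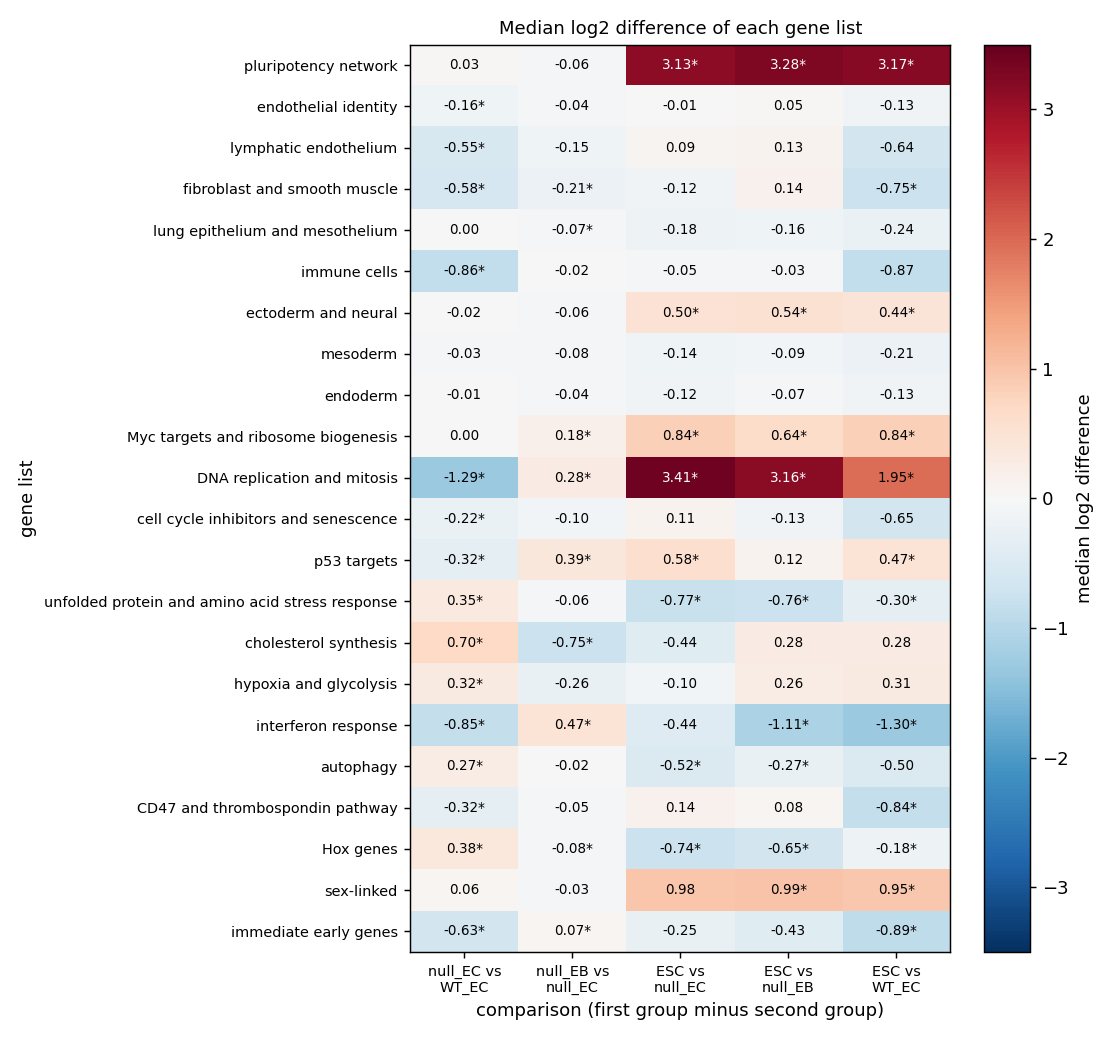
Median log2 difference of the members of each gene list (rows) in each comparison (columns), with color for direction and an asterisk for a camera adjusted p below 0.05 at the preset correlation. DNA replication and mitosis stood at -1.29 in null_EC against WT_EC and at 3.41, 3.16 and 1.95 in the ESC comparisons.

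Embryoid bodies formed by the null cells differed from the null cells most clearly in p53 targets, which rose. Of 25 measured targets 8 rose and 0 fell (14 adjusted over the list alone), with the TNF family receptor Eda2r 4.24-fold higher (9.82 ± 0.130 against 7.73 ± 0.139, adjusted p = 0.000127) and Phlda3, an inhibitor of Akt, 2.25-fold higher (11.53 ± 0.0970 against 10.36 ± 0.0653, adjusted p = 0.000492). The list median was 0.39, and this was the list whose call held with an estimated correlation (camera adjusted p = 5e-09; adjusted p = 0.0310 with an estimated correlation, fry adjusted p = 0.000279). In cholesterol synthesis 1 of 21 genes was called lower, Sqle (2.12-fold, adjusted p = 0.0389), 20 did not pass, and 10 lower adjusted over the list alone, at a median of -0.75 (camera adjusted p = 1.63e-08; adjusted p = 0.700 with an estimated correlation). The call of Sqle was lost with the housekeeping shift and without null_EC 1, null_EC 3, null_EB 2, null_EB 3 or any ESC array.

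Among single genes, the VEGF receptor Kdr fell 10.3-fold to 7.34 ± 0.0718 (adjusted p = 8.04e-06) and Podxl fell 7.43-fold (adjusted p = 8.58e-06), while Calcrl rose 3.72-fold (adjusted p = 0.000323). The endothelial identity list had 2 of 44 higher and 2 lower (3 and 3 adjusted over the list alone) and did not pass (camera adjusted p = 0.219). The largest decrease was in the acute phase gene Saa3 (15.3-fold, 7.19 ± 0.183 against 11.12 ± 0.178, adjusted p = 0.000323). Other large decreases were in the matrix genes Col12a1 (8.63-fold, adjusted p = 0.000264) and Nid2 (6.66-fold, adjusted p = 0.000323), the drug efflux pump Abcb1b (7.03-fold, adjusted p = 4.9e-06), Dock8 (6.83-fold, adjusted p = 0.00150) and Rasl11b (6.68-fold, adjusted p = 0.00471). The largest increases were in the placental prolactin relative Prl2c5 (11.16 ± 0.0419 against 7.65 ± 0.170, adjusted p = 0.0430), Nxf3 (8.43-fold, adjusted p = 4.7e-07) and Ugt2b34 (5.53-fold, adjusted p = 4.7e-07). They were followed by the iron exporter Slc40a1 (5.41-fold, adjusted p = 0.000381), the tetraspanin Cd53 (5.28-fold, adjusted p = 0.0291), the co-stimulatory ligand Cd80 (5.09-fold, adjusted p = 0.000924) and the prostaglandin synthase Ptgs2 (4.20-fold, adjusted p = 0.0231). The calls of Prl2c5, Cd53 and Ptgs2 were lost on leaving out any null_EC or null_EB array, that of Cd53 also without ESC 1 or ESC 3, and that of Prl2c5 in further settings.

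The other lists that passed did so at the preset correlation only. Among immediate early genes 5 of 32 rose and 0 fell (8 and 1 adjusted over the list alone), with the phosphatase gene Dusp6 2.04-fold higher (adjusted p = 0.00159) beside Klf4 and Myc (list median 0.07, camera adjusted p = 0.0315; adjusted p = 0.745 with an estimated correlation). This list call was also lost with the housekeeping shift, with array weights, with the 6 arrays alone, without the WT_EC arrays, and without WT_EC 2, WT_EC 3 or null_EB 1. DNA replication and mitosis had a median of 0.28 (camera adjusted p = 4.64e-06; adjusted p = 0.743 with an estimated correlation), yet limma called 0 of its 44 members, and 10 were higher and 1 lower at an unadjusted p below 0.05. The interferon response had a median of 0.47 with 0 of 31 called and 4 higher at an unadjusted p below 0.05 (camera adjusted p = 0.000148; adjusted p = 0.745 with an estimated correlation). Its array medians did not overlap, at 9.59 to 9.76 in null_EB and 9.01 to 9.25 in null_EC. Ifit3 was apart as well (11.07 to 11.26 against 9.301 to 9.871), whereas Zbp1 overlapped. The pooled error includes the WT_EC arrays, with interferon medians of 9.92 on WT_EC 1 and 11.08 on WT_EC 2. The lack of calls therefore does not show that no member rose. Myc targets and ribosome biogenesis had a median of 0.18 with 1 of 45 higher, the telomerase gene Tert (1.45-fold, adjusted p = 0.0186), and 1 lower, the transferrin receptor Tfrc (1.49-fold, adjusted p = 0.0281; camera adjusted p = 0.000566; adjusted p = 0.745 with an estimated correlation). Fibroblast and smooth muscle genes had 4 of 38 lower and 1 higher (5 and 2 adjusted over the list alone). The collagen crosslinking gene Lox was 2.22-fold lower (adjusted p = 0.0110) and Snai2 2.97-fold higher (adjusted p = 0.0270). The list median was -0.21 (camera adjusted p = 0.00356, and 0.737 with an estimated correlation). The array medians overlapped, at 9.21 to 9.36 in null_EB and 9.17 to 9.31 in null_EC. The mesothelial genes Lrrn4 and Wt1 fell 3.29-fold (adjusted p = 0.00487) and 1.67-fold (adjusted p = 0.00908), the 2 called members of the lung epithelium and mesothelium list (camera adjusted p = 0.00951; adjusted p = 0.575 with an estimated correlation), whose median of -0.07 turned to 0.01 with the housekeeping shift. Of the 9 mesothelium genes listed after the values had been seen, 4 were lower and 0 higher, with a median of -0.92. Hox genes had 2 of 37 lower (3 adjusted over the list alone), Hoxc13 (1.69-fold, adjusted p = 0.00614) and Hoxa4 (1.41-fold, adjusted p = 0.0249; camera adjusted p = 0.0152; adjusted p = 0.575 with an estimated correlation).

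The pluripotency network did not pass in null_EB against null_EC (median -0.06, camera adjusted p = 0.3). Besides Klf4, 1 of its 39 members was called, the alkaline phosphatase gene Alpl, a stem cell marker, which fell 3.66-fold (7.59 ± 0.210 against 9.46 ± 0.435, adjusted p = 0.000530), and 37 did not pass. Germ layer lists did not pass either: 0 of 26 ectoderm and neural genes, 0 of 23 endoderm genes and 1 of 26 mesoderm genes were called, Myl7 at 1.95-fold lower (adjusted p = 0.00433). At an unadjusted p below 0.05 limma gave 0, 2 and 3 genes of these lists. The hypoxia and glycolysis list was near the threshold (camera adjusted p = 0.0513) and was called lower with the housekeeping shift, array weights, the 6 arrays alone and several other settings. In the CD47 and thrombospondin pathway, which did not pass as a list (median -0.05), 2 of 20 genes were higher and 2 lower (2 and 5 adjusted over the list alone). The integrin genes Itgb3 (2.63-fold, adjusted p = 0.00541) and Itga6 (1.89-fold, adjusted p = 0.0144) rose, and Kdr (10.3-fold, adjusted p = 8.04e-06) and the thrombospondin gene Thbs2 (3.71-fold, adjusted p = 0.0287) fell.

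Of the genes named in these lists, Snai2, Hoxa4 and Thbs2 lost their calls on leaving out any null_EC or null_EB array, and Tert and Tfrc on leaving out any of these except null_EB 1. Hoxa4, Thbs2, Tert and Tfrc also lost them with the housekeeping shift, and Itga6 and Lox without null_EC 2 or null_EB 2, among others.

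In all, 1077 genes were called in null_EB against null_EC, 578 higher and 499 lower, with 245 at least 2-fold (85 higher, 160 lower), and in every called gene the groups did not overlap. The share of calls that were higher was 53.7%, against 61.6% with the housekeeping shift and 44.5% with cyclic loess (488 higher, 609 lower), so here too the balance depended on the scaling. Camera called 9 of the 22 lists. The spread of the WT_EC arrays enters the shared error, and the count was 5464 with the 6 arrays alone. It was 8001 with array weights, which also weigh the compared arrays unequally, from 0.769 for null_EB 1 to 8.39 for null_EB 2. It was 5058 in the fit without the WT_EC arrays, which was added after the data had been seen. Each of these held all 1077. It was 602 with the housekeeping shift. It ran from 436 to 496 without a null_EC array, from 390 to 676 without a null_EB array and from 1828 to 2676 without a WT_EC array.

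**Figure D3:**
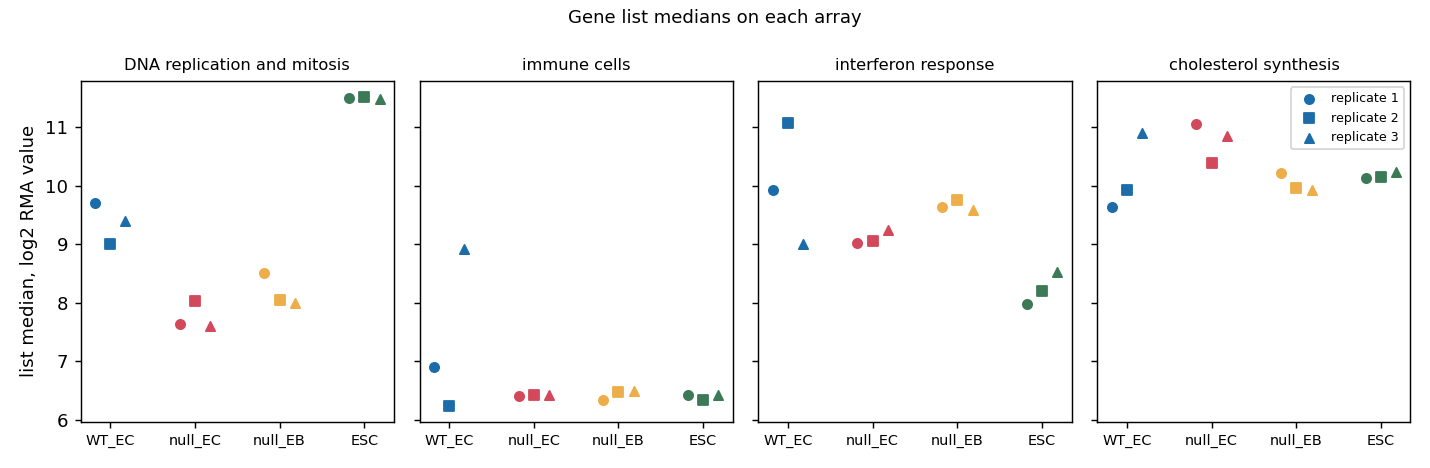
Median log2 signal of 4 gene lists on each of the 12 arrays, grouped by sample group. The immune cells median was 8.92 on WT_EC 3 and below 7 on every other array, and the DNA replication and mitosis median was between 9.01 and 9.71 in WT_EC and between 7.60 and 8.03 in null_EC.

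The stem cell line served as a reference for pluripotent cells. Camera called 8 of the 22 lists against null_EC, 9 against null_EB and 12 against WT_EC. The endothelial identity list passed in none of them in the principal fit (camera adjusted p = 0.803, 0.395 and 0.208). Against WT_EC more lists passed without WT_EC 2 (15) and with array weights (20). Against null_EB, 37 of the 39 pluripotency network genes were higher in ESC and 2 lower, Klf4 (2.07-fold, adjusted p = 0.000883) and Fut4, of low signal (1.24-fold, adjusted p = 0.0157), with the same counts adjusted over the list alone. Tdgf1, a co-receptor of Nodal, was 109-fold higher (13.43 ± 0.111 against 6.66 ± 0.0499, adjusted p = 2.61e-12). The list median was 3.28 (camera adjusted p = 1.72e-28; adjusted p = 0.0373 with an estimated correlation). All 44 DNA replication and mitosis genes were higher, with Bub1 39.3-fold (12.39 ± 0.125 against 7.09 ± 0.401, adjusted p = 9.57e-08; camera adjusted p = 2.88e-26; adjusted p = 0.122 with an estimated correlation). Of the Myc targets 35 of 45 were higher and 0 lower, with Tfrc at 8.37-fold (adjusted p = 1.25e-08; camera adjusted p = 3.72e-10; adjusted p = 0.525 with an estimated correlation), while Myc itself was lower. Of the ectoderm and neural genes 16 of 26 were higher, with the transcription factor Otx2 at 49.7-fold (adjusted p = 3.25e-12; camera adjusted p = 9.56e-06; adjusted p = 0.471 with an estimated correlation).

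Lower in ESC than in null_EB were 24 of 38 unfolded protein and amino acid stress genes, with 3 higher (24 and 4 adjusted over the list alone). The cystine transporter Slc7a11 was 26.9-fold lower (adjusted p = 0.000335; camera adjusted p = 1.62e-05; adjusted p = 0.525 with an estimated correlation). Of 37 Hox genes 25 were lower and 3 higher, with Hoxa5 5.00-fold lower (adjusted p = 9.43e-06) and Hoxc8 2.62-fold higher (adjusted p = 0.000230; camera adjusted p = 0.000148; adjusted p = 0.122 with an estimated correlation). The interferon response had 18 of 31 lower and 0 higher, with Ifit3 at 8.96-fold (adjusted p = 0.000202; camera adjusted p = 0.00192; adjusted p = 0.931 with an estimated correlation). Autophagy had 15 of 31 lower and 2 higher, with the cargo receptor gene Sqstm1 at 2.86-fold lower (adjusted p = 1.49e-05; camera adjusted p = 0.00595; adjusted p = 0.580 with an estimated correlation). Of 6 sex-linked genes 4 were higher and 1 lower (camera adjusted p = 0.0286, and 0.360 with an estimated correlation). The Y-linked genes Eif2s3y and Uty were at 9.39 and 9.64 in ESC and at low signal in null_EB (adjusted p = 6.41e-10 and 4.47e-11). Xist, the RNA that silences an X chromosome, was 5.29-fold lower (adjusted p = 1.98e-08). Its signal still lay between 10.72 and 11.055 on the ESC arrays, above the median of all tested values (8.01), alongside the Y-linked genes. Whether the ESC samples held more than 1 kind of cell was not tested, so differences from ESC may include other cells. The mesothelial genes Upk3b and Msln were 20.8-fold and 17.9-fold lower in ESC (adjusted p = 3.31e-07 and 8.34e-08), and the epithelial genes Epcam and Cdh1 were 43.6-fold and 24.1-fold higher (adjusted p = 8.5e-11 and 4.17e-10), while their shared list did not pass (camera adjusted p = 0.600).

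The 3 largest increases were the same genes in each ESC comparison. Folds against groups of low signal, as for Apela, Pou5f1, Sox2 and Nanog, are limited by background and are lower bounds at best. Apela, a peptide ligand of the apelin receptor, was 146-fold higher than in null_EC, 145-fold higher than in null_EB and 157-fold higher than in WT_EC (12.36 ± 0.00166 in ESC against 5.17 ± 0.0341, 5.18 ± 0.146 and 5.07 ± 0.160, adjusted p = 2.57e-12, 2.61e-12 and 2.19e-12), followed in each by the zinc finger gene Zfp980 and Tdgf1. The retinal dehydrogenase Aldh1a1 was 83.6-fold lower in ESC than in null_EC (adjusted p = 2.05e-07), Pkhd1l1 72.2-fold lower than in null_EB (adjusted p = 2.53e-05) and Cxcl13 118-fold lower than in WT_EC (adjusted p = 4.36e-10). Against null_EC the pluripotency network had 37 of 39 higher and 1 lower (camera adjusted p = 4.59e-27; adjusted p = 0.0437 with an estimated correlation), and against WT_EC 36 higher and 1 lower (camera adjusted p = 8.16e-27; adjusted p = 0.0449 with an estimated correlation). DNA replication and mitosis had 43 of 44 higher against null_EC and 44 of 44 against WT_EC (adjusted p = 0.122 and 0.339 with an estimated correlation), and Myc targets had 37 and 39 of 45 (adjusted p = 0.409 and 0.339 with an estimated correlation). Against WT_EC the immediate early genes also passed, with 18 of 32 lower and 1 higher in ESC (camera adjusted p = 0.000373; adjusted p = 0.339 with an estimated correlation), as did fibroblast and smooth muscle genes, with 19 of 38 lower and 3 higher (camera adjusted p = 0.00293; adjusted p = 0.366 with an estimated correlation). The p53 targets were higher in ESC than in null_EC (14 of 25 higher, 2 lower, camera adjusted p = 0.000784; adjusted p = 0.137 with an estimated correlation) and in WT_EC (13 higher, 4 lower, camera adjusted p = 0.0320; adjusted p = 0.339 with an estimated correlation, 0.0679 without dim genes and 0.0676 with cyclic loess), and did not pass against null_EB (camera adjusted p = 0.382). The pluripotency network was the list that held with an estimated correlation in each.

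Against null_EC 9560 genes were called in ESC (4556 higher, 5004 lower; 1867 and 1421 at least 2-fold), against null_EB 8929 (4338 and 4591; 1717 and 1268 at least 2-fold) and against WT_EC 9394 (5065 and 4329; 1862 and 1260 at least 2-fold), and the groups did not overlap in 9535, 8884 and 8867 of them. The share of calls higher in ESC was 47.7%, 48.6% and 53.9%, against 37.8%, 28.9% and 29.5% with the housekeeping shift and 57.8%, 60.0% and 53.5% with cyclic loess. Against WT_EC the fold of 13 of the 92 genes named by the rule changed by more than 1.5 times when 1 array was left out, and in the other 2 comparisons of none. The housekeeping shift moved the median of all genes from -0.09 to -0.25, from -0.08 to -0.32 and from -0.07 to -0.34 in these 3 comparisons, and from 0.03 to -0.08 in null_EC against WT_EC, so smaller differences are to be read relative to it.

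**Figure D4:**
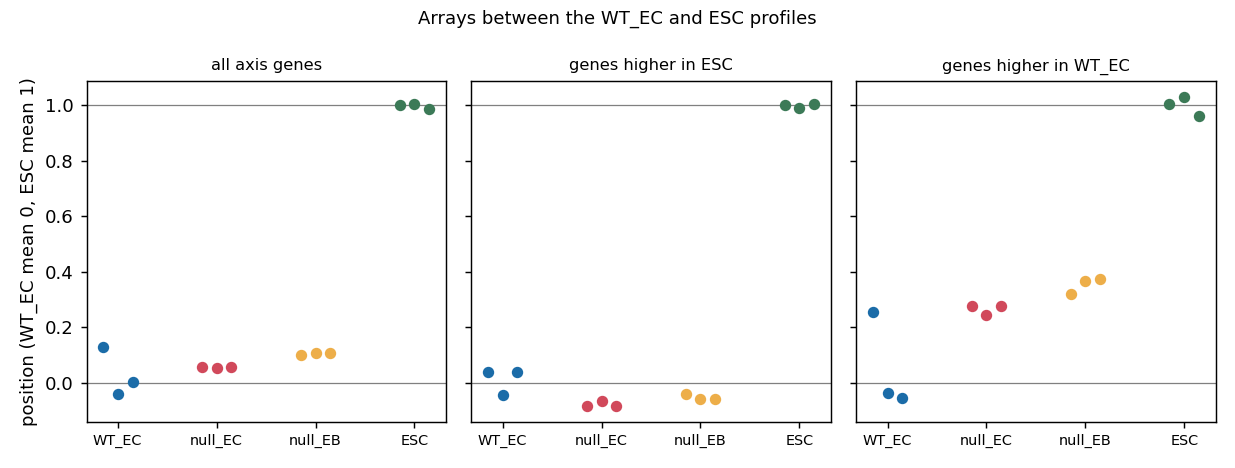
Position of each array on the line from the WT_EC mean (0) to the ESC mean (1), over all 790 axis genes, the 469 higher in ESC and the 321 higher in WT_EC. The null_EB arrays lay at 0.098 to 0.108 over all genes, beside 0.052 to 0.055 for null_EC and -0.042 to 0.129 for WT_EC.

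How far the null cells and embryoid bodies lay from WT_EC toward the stem cell line was asked over 790 genes at least 4-fold different between WT_EC and ESC. On this scale null_EC lay at 0.0539 ± 0.00140 and null_EB at 0.104 ± 0.00534, with the WT_EC arrays at 0.0301 ± 0.0887. All 3 null_EB arrays lay above all 3 null_EC arrays (exact p = 0.1, 2-sided, the smallest p possible), and null_EB and WT_EC overlapped (exact p = 0.4). Over the 469 genes higher in ESC, which include Pou5f1, Sox2 and Nanog, null_EC and null_EB lay slightly away from ESC, at -0.0794 ± 0.00983 and -0.0532 ± 0.00936 (exact p = 0.1 between them). Over the 321 genes higher in WT_EC they lay at 0.265 ± 0.0192 and 0.354 ± 0.0285 (exact p = 0.1). The axis genes were picked on the same WT_EC arrays, and WT_EC 1 itself lay at 0.256 over the genes higher in WT_EC. The positions do not measure endothelial identity. In ESC against WT_EC the 18 endothelial core genes had a median of -0.06, with 3 called higher and 4 lower. Of 15 mesothelium genes, listed after the values had been seen, 13 were called at least 2-fold lower in ESC. Leaving out WT_EC 2 moved null_EC to 0.149 and null_EB to 0.206 over all axis genes, to 0.433 and 0.531 over those higher in WT_EC, and to -0.0557 and -0.0279 over those higher in ESC.

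Genes called in both null_EC against WT_EC and null_EB against null_EC mostly changed in opposite directions. Of these 465 genes, out of 2615 and 1077 called, 244 were higher in null_EC and lower in null_EB, where independent calls would give 40.5, and 143 were lower in null_EC and higher in null_EB, against 28.9. Itm2a, Podxl, Gabrb1, Adgrg1, Emx2 and Kdr were among the former, with Itm2a at 3.71 and then -2.71 and Podxl at 2.99 and then -2.89 on the log2 scale. Calcrl, Cd80, Eda2r and Ptgs2 were among the latter, with Calcrl at -2.55 and then 1.90. The other 53 and 25 were higher or lower in both, near the 46.9 and 24.9 of independent calls. The null_EC arrays stand in both comparisons with opposite sign, which alone gives a negative relation. In 100 simulations of unchanged groups the correlation across genes was -0.252 at the median, against -0.286 observed. The lowest simulated correlation was -0.274. The covariance was -0.00446, against -0.0408. No simulation called a gene in both comparisons, and at most 1 was called in null_EB against null_EC. The simulated groups held no changed genes, so they cannot show what overlap the shared arrays give among real changes. The counts from independent calls leave out the shared arrays too. There were only 3 null_EC arrays, too few to divide between the comparisons. The count of shared genes was 1160 without WT_EC 2, 1118 without WT_EC 1, 859 without WT_EC 3 and from 197 to 302 without a null_EC or null_EB array.

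Of 870 genes called in both null_EB against null_EC and ESC against null_EC, 309 were higher and 393 lower in both, against 132 and 125 from independent calls, and 32 and 136 went in opposite directions. Kdr (-3.36 in null_EB, -3.79 in ESC), Saa3 (-3.93 and -4.44) and Dock8 (-2.77 and -3.72) were lower in both, whereas Myc rose in null_EB (0.75) and was lower in ESC (-1.58). Here too the shared null_EC arrays alone give a positive relation. The simulated correlation was 0.469, above the 0.339 observed, and the simulated covariance 0.00444, below the 0.0963 observed. No simulation called a gene in both comparisons, and at most 1 was called in null_EB against null_EC. The simulated groups held no changed genes, so they cannot show what overlap or correlation real changes would give. The counts from independent calls leave out the shared arrays here as well. The shared count was 2214 without WT_EC 1, 1815 without WT_EC 2, 1499 without WT_EC 3, and from 327 to 562 without a null_EC, a null_EB or the ESC 1 array.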

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

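The alternatives were chosen before the data were examined, except the fit without the WT_EC arrays, which was chosen after seeing the data. No gene or list called in either setting changed the direction of its test, while some list medians and some values that passed in neither setting changed sign. Of 8134 tests of named genes under an alternative, 7700 kept their side of the threshold, 427 lost and 7 gained a call. Of 2376 tests of gene lists, 2249 kept their side, 90 lost and 37 gained a call.

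With an estimated correlation between genes, camera called 0 lists in null_EC against WT_EC (6 at an unadjusted p below 0.05, and 9 by fry) and 1 in each of the other 4 comparisons, where the preset correlation gave 15 and 9, 8, 9 and 12. The estimated correlation enters the variance of each list, which is how it ends calls by construction. With the housekeeping shift 1541 genes were called in null_EC against WT_EC (693 higher, 848 lower) and 602 in null_EB against null_EC. The cause was not tested. Array weights gave 8001 genes in null_EB against null_EC, 375 of them at least 2-fold, 14866 in ESC against null_EB, and 20 lists in ESC against WT_EC. The weights of the WT_EC arrays were 0.0897, 0.131 and 0.371, which lowers their share in the common error, but the weights of the compared arrays differed as well (null_EB 1 at 0.769, null_EB 2 at 8.39), and the effects were not separated.

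Fitting the 6 arrays of each comparison alone gave 588 genes in null_EC against WT_EC, 324 of them at least 2-fold, 5464 in null_EB against null_EC and 6250 in ESC against WT_EC. Without the WT_EC arrays 5058 genes were called in null_EB against null_EC. The spread of the WT_EC arrays no longer enters the other comparisons in these fits, and in those with WT_EC it is no longer averaged with the tighter groups. In null_EC against WT_EC 32 of 65 named genes lost their call with 6 arrays, and in null_EB against null_EC 0 of 49 did.

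Leaving out each array in turn gave 1335 genes (without null_EC 1) to 5435 (without WT_EC 2) in null_EC against WT_EC, with 1648 without null_EC 2 and 1449 without null_EC 3, and 478 to 1134 at least 2-fold, the highest without WT_EC 2. In null_EB against null_EC it gave 390 (without null_EB 2) to 2676 (without WT_EC 1), and also 2187 without WT_EC 2, 1828 without WT_EC 3, 496, 442 and 436 without null_EC 1, null_EC 2 and null_EC 3, and 676 and 432 without null_EB 1 and null_EB 3. At least 2-fold were 149 (without null_EB 2) to 318 (without WT_EC 2), with 158 without null_EC 2 and 156 without null_EB 3. In the 3 ESC comparisons the counts stayed within 1.5 times.

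The positions over all axis genes were 0.0487 for null_EC with dim genes left out, and 0.0779 for null_EC and 0.134 for null_EB with every probe set by itself. Every probe set by itself gave -0.0653 and -0.0393 over genes higher in ESC and 0.289 and 0.389 over genes higher in WT_EC. The housekeeping shift gave 0.107 and 0.160 over all axis genes and -0.100 for null_EC over genes higher in ESC. Cyclic loess gave -0.105 and -0.0839 over genes higher in ESC and 0.285 and 0.383 over genes higher in WT_EC. With axis genes at least 2-fold different the positions were 0.0443 and 0.116, -0.0593 and -0.00923, and 0.203 and 0.307. Without the pluripotency, endothelial identity and DNA replication lists they were 0.0683 and 0.124 over all axis genes. Leaving out each array gave 0.0440 to 0.149 and 0.0947 to 0.206 over all axis genes, -0.0847 to -0.0557 and -0.0561 to -0.0279 over genes higher in ESC, and 0.243 to 0.433 and 0.332 to 0.531 over genes higher in WT_EC, for null_EC and null_EB. The highest value was without WT_EC 2 in each. The cause was not tested.

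Of the genes called in both null_EC against WT_EC and null_EB against null_EC, 97 were at least 2-fold in both, and leaving out each array gave 197 (without null_EC 3) to 1160 (without WT_EC 2). For ESC against null_EC with null_EB against null_EC these were 146, and 327 (without null_EB 2) to 2214 (without WT_EC 1). A stricter fold leaves fewer genes by construction.

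With a replicate block the 5 comparisons gave 2239, 764, 9149, 8537 and 8954 genes, all within 1.5 times. Of 18 pairs of arrays with the same number in different groups 3 correlated above 0.1 after the group means were removed. Their range was -0.256 to 0.225 and their median -0.0382, and the other 36 pairs had a median of 0.00292. The numbers thus gave no clear sign of pairing. Deviations within a group offset each other, so the other pairs are no independent baseline and pairing cannot be ruled out. The files hold no detection calls, so the values do not show whether genes of low signal were expressed. The number of arrays limits precision.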

Other observations

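The marker lists below and the tests of both patterns were chosen only after the result was seen, except both tests of scaling, which were written before their values were seen, and the splits of the arrays, which were planned.

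The arrays of all endothelial groups held high signals of genes known from mesothelium, the lining of lung and chest wall. Msln was at 11.67 in WT_EC, 12.14 in null_EC, 12.01 in null_EB and 7.84 in ESC, and Upk3b at 11.95, 13.05, 12.13 and 7.75. Lrrn4 (11.15, 12.22, 10.50 and 8.58) and Wt1 (10.81, 11.43, 10.69 and 7.72) were likewise highest in null_EC and lowest in ESC. Over the 9 tested mesothelium genes the median was 0.52 with 4 called higher in null_EC against WT_EC, and -0.92 with 4 called lower in null_EB against null_EC. The members ran from -2.85 (Aldh1a2) to 1.41 in the former. Of the endothelial genes, Pecam1 was at 6.94, 6.59, 6.56 and 8.86, Vwf at 8.13, 7.91, 7.90 and 8.11, and Cdh5 at 9.10, 6.85 and 9.52 on the WT_EC arrays and 7.16, 7.05 and 6.97 in null_EC, null_EB and ESC. These genes were chosen after their values were seen.

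Over 9 tested mesothelium genes, 4 of which stand in lists fixed before, the median of null_EC minus ESC was 2.81 on the log2 scale, and 7 of the 9 were called. Aldh1a2 was an exception, high on WT_EC 1 and WT_EC 3 (10.48 on the latter), at 5.77 on WT_EC 2, and below 6.4 on each null_EC, null_EB and ESC array, and in the wider list of 15 Calb2 was another, at 5.66, 5.79 and 5.75 in WT_EC, null_EC and null_EB and 6.34 in ESC. The lower of the medians after cyclic loess and after the housekeeping shift was 2.75. These alternatives moved the median of all genes in ESC against null_EC only from -0.09 to 0.00018 and -0.25. The difference was thus far larger than either shift, but the check could hardly have come out otherwise and says little on other scaling. Mesothelial cells in the lung preparations may be a source of these transcripts. Endothelial cells that gained the genes in culture cannot be told apart from this, because no lung endothelial sample taken before culture was analysed here, and the 18 endothelial core genes, all in lists fixed before, had a median of -0.06 in null_EC minus ESC.

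The 3 WT_EC arrays differed from each other more than the arrays of any other group. The difference of WT_EC 3 from the mean of WT_EC 1 and WT_EC 2, taken gene by gene, had a median of 1.79 over the immune cells list, and of the macrophage list, 13 of whose 15 genes stand in lists fixed before, Lyz2 was at 9.05, 5.44 and 12.31, Laptm5 at 7.63, 6.72 and 11.27 and Tyrobp at 7.84, 6.75 and 10.94 on WT_EC 1, WT_EC 2 and WT_EC 3. Immune cells in that sample may account for the immune genes, but not for the whole spread, since WT_EC 1 and WT_EC 2 correlated at 0.954. The median SD of the WT_EC genes was 0.199 after cyclic loess, against 0.213 before. The deposited values were already quantile normalized, so this hardly tests scaling as a cause. A CD47 null sample in the place of WT_EC 2 cannot be told apart from a difference between animals or cultures, which was not tested: over 1134 genes called at 2-fold or more without it, WT_EC 2 lay at a median of 0.599 between WT_EC 1 and WT_EC 3 (0) and null_EC (1), where the null_EB arrays lay at 0.910 to 0.927. It was nearer null_EC by its correlations (0.977 against 0.961 with its own group) and its Cd47 signal (11.29, against 10.98 to 11.11 in null_EC and 12.59 and 12.48 on WT_EC 1 and WT_EC 3), and nearer WT_EC by its DNA replication and mitosis median (9.01) and by Cxcl13 (13.01, against 6.71 to 7.04 in null_EC), Serpina3n (13.28, against 8.88 to 9.40), Lcn2 (13.04), Adam23 and Gabrb1 (7.05), genes named with WT_EC 2 counted as wild type.

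For 3 arrays against 3 there are 10 splits, so the share of splits with a result as large is never under 0.1, too few to judge chance. With the 6 arrays alone the real split gave 588, 5464, 13304, 12306 and 6250 genes in null_EC against WT_EC, null_EB against null_EC, ESC against null_EC, ESC against null_EB and ESC against WT_EC. It gave 324, 347, 3336, 3025 and 2846 genes at least 2-fold. In limma the highest of the other splits gave 0 in each, and 619, 930, 117, 369 and 292 genes at an unadjusted p below 0.05, where the real split gave 3358, 7339, 13931, 13100 and 8338. So 1 of 10 splits gave as many genes in each comparison. For gene list tests the real split gave 14, 10, 8, 9 and 11 lists and the highest of the others 15, 14, 11, 11 and 15, with 2, 3, 4, 4 and 4 of the 10 splits giving as many.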
